A study of Mus musculus with 30 samples.

How the data were processed

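RNA sequencing had been carried out on 30 libraries of mouse bone marrow-derived macrophages, 21 from 7 cultures given the vehicle DMSO and 9 from 3 cultures given the β2 adrenergic agonist metaproterenol hemisulfate (MPH). Total RNA was extracted and libraries were made with a TruSeq kit, per the labels' protocols. The tools FastQC, cutadapt, HISAT2 and SAMtools and the mouse genome build mm9 are named without versions, per the submitters' processing notes. The program that counted reads, its annotation, its use of strand and its handling of reads that map to several places are not given in the sources used here. The deposited table gives RPKM values (mapped reads scaled by transcript length and by library depth), computed by the authors, with 1 line for each of 44401 RefSeq transcripts. These lines carry 24761 gene symbols, of which 8852 have more than 1 line. All value columns matched 1 library each by name. A 6 h time named in the design text was not analysed here.

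Depth was estimated from the steps between low values. Over 8198 transcripts whose values stayed below 0.1 RPKM, 99.9% of the values were whole multiples, within 0.01, of the smallest value of that transcript and library. No value equalled 0, so a transcript without reads holds the value of 1 step and low values are upper limits. With transcript lengths taken from a GENCODE M21 annotation, used for names and lengths because its build differs from that of the files, the steps gave about 5.4 to 92.1 M reads per library (M, mega), with a median of 41.3 M. The design text gives a minimum of 20 M raw reads; 7 libraries had fewer by this estimate, which covers reads counted by the authors and not raw reads. The libraries of D6, UKD and D4 at 1 h had about 5.4, 8.5 and 9.7 M reads. A single read in a transcript of 2 kb stood for 0.005 RPKM in the deepest library and 0.093 RPKM in the shallowest. No 2 libraries were copies of each other. The lowest mean chi-square between approximate read counts of 2 libraries of the same time was 14.2, where counting error alone gives 1.

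For each gene symbol the transcript with the highest mean RPKM over all libraries was kept. Values were analysed as log2(RPKM + 0.5), a scale on which fold changes of genes with low values are understated. Genes with at least 1 RPKM in at least 3 libraries of the fit were tested with limma-trend (limma 3.58.1, R 4.3.3), and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A single fit of the 21 libraries of D3 to D6 and M2 to M4 (10239 genes), with a mean for each treatment and time, gave the comparisons of MPH with DMSO, the LPS responses under MPH and the differences between LPS responses. A fit of the 21 DMSO libraries (10212 genes) with the name series (D, UKD or r) as a covariate gave the LPS response under DMSO. The UKD, r1 and r2 cultures entered the comparison with MPH only as an alternative, because no MPH culture shares their names. Il1b was also compared at each time with an exact two-sided permutation test of the difference of means. Every p or adjusted p given for a gene comes from limma unless an exact test is named, and each ± is an SD over libraries unless named SE.

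Lists of genes were fixed before the data were examined, as were the groups, the tests, the alternative settings and the rule for named genes. All lists except 1 were matched in full, with 375 of 376 symbols found and 2 of these under another symbol. Of the 23 lists, 19 had at least 3 members in a fit and were tested, and the lists of B cell, T and NK cell, stromal, and erythroid and mast cell markers had fewer. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. Camera compares a list with all other genes, whereas fry tests whether the genes of a list move, on balance, in 1 direction, and its mixed form whether they change in either direction. Fry is printed for some lists only. It called 2, 0 and 1 of the 19 lists for MPH against DMSO at 0, 1 and 2 h. For the differences between LPS responses it called 0 at 1 h and 0 at 2 h. Lists of up to 200 genes that rose or fell most after LPS in UKD, r1 and r2 alone were tested in the comparisons of MPH with DMSO, with which they share no library. Named genes are Il1b, the 10 largest rises and 10 largest falls past the threshold whose groups do not overlap (for LPS, changed in 1 direction in every culture), up to 4 members of each list past the threshold with the smallest p, and the 5 smallest p where fewer than 5 genes passed. Some genes that this rule selects are not reported here. Other genes named in the text were chosen after their values were seen.

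Each test was run on simulated data with the same libraries and numbers of genes, in which 200 genes had been changed. Noise was drawn independently for each gene and library, without the correlation between genes or between libraries of a culture seen in the real values. The shares and list calls below therefore do not show how the tests behave under such correlation. Of genes changed by 1 on the log2 scale, 59.0%, 64.0% and 66.0% were called for MPH against DMSO at 0, 1 and 2 h, and 93.0%, 90.0% and 91.0% of genes changed by 2. For the differences between LPS responses at 1 and 2 h these shares were 27.0% and 31.0% at a change of 1 and 84.0% and 74.0% at a change of 2. For LPS under DMSO they were 87.0% and 92.0% at a change of 1, with 100% and 97.0% at a change of 2. Under MPH they were 57.0% and 54.0% at a change of 1 and 84.0% and 90.0% at a change of 2. A list of 18 genes shifted by 0.7 was called by camera and fry in each comparison, and an unshifted list in none.

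The libraries of a culture, named in the titles at all 3 times, deviated together from their group means. Their correlations lay between 0.628 and 0.914 for DMSO and between 0.673 and 0.824 for MPH. A fit with the culture as a block was therefore run for the LPS comparisons. It is given where it moved a call of a named gene or of a list by camera, but not for every count of list members. Nothing in the labels says which cultures came from different animals, and part of the spread between cultures may be technical. The main fits had no term for the culture and took the libraries of a culture as independent. Their p-values therefore do not measure the spread between cultures alone. Alternatives covered the pseudocount, the filter, the scaling of libraries, the choice of DMSO cultures, weights, covariates and the removal of each culture. After the 1 h library labelled M4 was seen to stand apart, removal of single libraries and of the shallowest ones, and a covariate for the sex of the culture, were added. Reads shared between near-identical genes could not be told apart, so values of such families are uncertain. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.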

Results

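Gene expression was measured in macrophages grown from the bone marrow of wild-type C57Bl/6 mice with the growth factor M-CSF. The cells were given 2 h of DMSO or of 1 µM MPH, a drug that activates β2 adrenergic signalling, which raises cyclic AMP (cAMP). They then received lipopolysaccharide (LPS), a bacterial product sensed by Toll-like receptors, labelled as 100 ng/µL, for 0, 1 or 2 h. The DMSO cultures D3, D4, D5, D6, UKD, r1 and r2 and the MPH cultures M2, M3 and M4 each gave 1 library per time. Comparisons of MPH with DMSO used 3 MPH and 4 DMSO cultures (D3 to D6), and the LPS response under DMSO used 7. Approximate depth ran from 5.4 to 92.1 M reads, and the 1 h libraries of D6, UKD and D4 were the shallowest.

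The series asks how β2 adrenergic signalling changes transcription of Il1b, which encodes the cytokine interleukin-1β. At 2 h of LPS, Il1b stood at 1660 ± 240 RPKM (SD, n = 3) with MPH and at 554 ± 184 RPKM (SD, n = 4) with DMSO. This difference of 1.63 on the log2 scale (SE 0.68) had an exact permutation p = 0.0286, the smallest that 35 arrangements can give, and all 3 MPH cultures lay above all 4 DMSO cultures. At 0 h Il1b was at 3.92 ± 4.81 RPKM with MPH and 0.618 ± 0.736 RPKM with DMSO, a log2 difference of 1.63 (exact permutation p = 0.114). Only 1 MPH culture lay above all 4 DMSO cultures there. At 1 h the means were 567 ± 404 and 252 ± 126 RPKM, a log2 difference of 0.92 (exact permutation p = 0.343). The 1 h library labelled M4 was at 133 RPKM, and the log2 difference without it was 1.76 (exact permutation p = 0.133, 2 against 4). After adjustment over all genes in limma none of these passed, with adjusted p = 0.571, 1 and 0.422 at 0, 1 and 2 h. The LPS responses of Il1b were not called different by treatment in that test, with interaction estimates of -0.71 at 1 h and 0.01 at 2 h (SE 0.96, adjusted p = 1 for both). These estimates depend on the pseudocount, the constant added to RPKM before the log, because Il1b was low at 0 h. With pseudocounts of 0.1 and 1 the log2 difference was 2.353 and 1.265 at 0 h, and 1.63 at 2 h with both. The 2 h difference was thus below the 0 h difference with the first and above it with the second. Against all 7 DMSO cultures the log2 difference was 1.79 at 0 h (exact permutation p = 0.025), 0.810 at 1 h (exact permutation p = 0.258) and 1.64 at 2 h (exact permutation p = 0.00833). The last is the smallest that 120 arrangements can give. All these exact tests take the cultures as interchangeable. That may not hold, because certain DMSO and MPH cultures deviated together in pairs, as given below. The 7 DMSO cultures may not be separate units either. Over expressed genes at 0 h UKD with D5 correlated at 0.9864 and r1 with r2 at 0.9885, where D3 with M2, 1 of those pairs, stood at 0.9816. The exact p-values against all 7 may therefore be too small. Without any 1 culture the difference at 2 h lay between 1.45 and 1.83, where exact p-values of 0.1 or 0.0667 are the smallest possible.

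**Figure D1:**
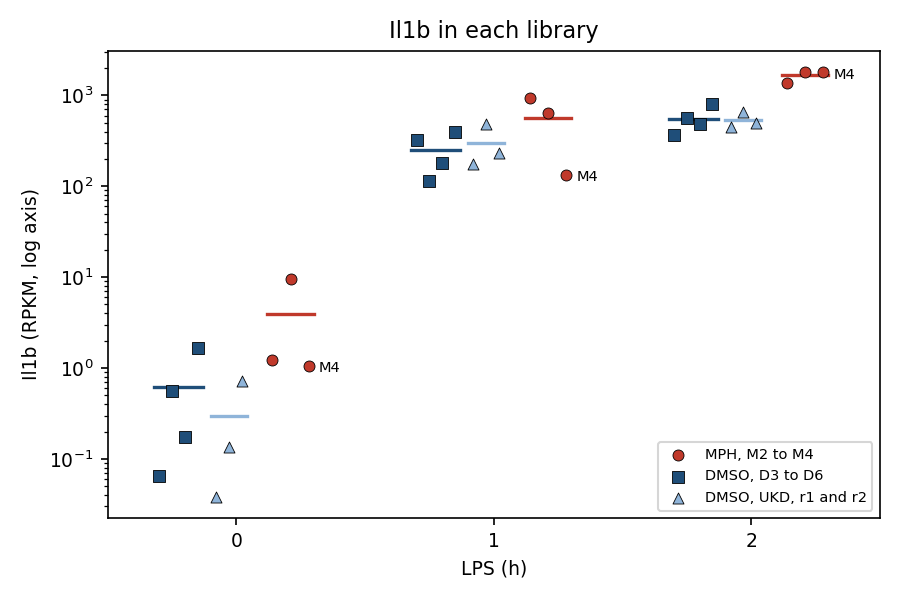
Il1b in RPKM (log axis) against hours of LPS, with 1 point per library, squares for D3 to D6, triangles for UKD, r1 and r2, circles for M2 to M4 and lines for group means. At 2 h the MPH libraries lie between 1390 and 1810 RPKM and the D3 to D6 libraries between 367 and 803 RPKM.

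Before LPS, MPH raised genes known as targets of cAMP signalling. Thbs1, which encodes the secreted matrix protein thrombospondin-1, rose from 5.50 ± 3.34 to 287 ± 95.3 RPKM, a log2 difference of 5.69 (SE 1.15, adjusted p = 0.0199). The orphan nuclear receptor gene Nr4a2 rose by 4.62 (SE 0.62), the cAMP-responsive modulator gene Crem by 3.87 (SE 0.80) and Pde4b, which encodes an enzyme that degrades cAMP, by 2.94 (SE 0.31). The largest fall was that of Ccl3, a chemokine gene, from 24.0 ± 15.8 to 1.82 ± 1.24 RPKM, or -3.31 (SE 0.61, adjusted p = 0.0107). Plau, the urokinase gene, fell from 83.2 ± 13.2 to 10.1 ± 1.41 RPKM, or -2.98 (SE 0.48, adjusted p = 0.0044). Other large rises were those of Dusp5 (4.04) and Nr4a1 (3.30) and of the AP-1 genes Fosl2 (3.75) and Fosb (3.67). So were those of Hilpda (3.66), which encodes a lipid droplet protein, and Vegfa (3.07), an angiogenic growth factor gene. Other large falls were those of Rasgef1b (-2.36), the potassium channel gene Kcnj2 (-2.07), the prostaglandin receptor gene Ptger4 (-1.69), Cdc42ep3 (-1.65), Rap2b (-1.47), the kinase gene Tec (-1.42, not past the threshold after median-of-ratios scaling), the homeobox gene Hhex (-1.33) and Ifi207 (-1.47). Ifi207 belongs to a family of similar genes, and its value is uncertain for that reason. Past the threshold were 89 of 10239 genes (limma), 69 higher and 20 lower, and 75 of these changed at least 2-fold. The groups did not overlap in 772 genes (7.54%, against 5.71% by chance). Here and at 1 and 2 h this share by chance takes the cultures as interchangeable. The pairs of DMSO and MPH cultures given below put that in doubt, so the distance from chance is uncertain. Of 30 named calls, 11 held when each culture was left out in turn (Cd14, Dusp5, Fosb, Fosl2, Nr4a2, Pde4b, Plau, Rap2b, Sik1, Vegfa and Zfp36). The call of Thbs1 held in 2 of the 7 cases. The count of genes was 45, 57 and 49 without the 0 h libraries of D4, D5 and D6, and 38, 48 and 36 without those of M2, M3 and M4. It was 165 without the 1 h library labelled M4 and 34, 31, 37, 48 and 33 without the whole cultures D4, D5, D6, M2 and M3. Against all 7 DMSO cultures it was 256 with a covariate and 213 without.

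By list, 9 of 18 cAMP/CREB target genes rose at 0 h, 0 fell and 9 did not pass. Adjusted over the list alone 13 rose and 1, Atf3 (-2.04), fell. Members that rose included Sik1 (2.29), which encodes a kinase regulated by cAMP, Pde4d (1.81) and Per1 (1.20). This list was higher as a whole (camera adjusted p = 2.97e-27, adjusted p = 0.00128 with an estimated correlation, fry adjusted p = 0.000135). Of 13 regulatory macrophage genes Thbs1 and Vegfa rose and 11 did not pass, with 3 higher adjusted over the list alone (camera adjusted p = 1.02e-07, adjusted p = 0.0284 with an estimated correlation). Of 20 MAPK immediate-early and feedback genes, Dusp5, Fosb and Ier3 (1.92) rose and 17 did not pass. Adjusted over the list alone 5 rose and 3 fell (camera adjusted p = 0.0113, adjusted p = 0.426 with an estimated correlation). Of 20 NF-kB feedback and family genes Zfp36 (1.95), which encodes an mRNA decay factor, and Cd83 (1.48) rose and 18 did not pass. Adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.000326, adjusted p = 0.426 with an estimated correlation). In the adrenergic and cAMP machinery list of 20, Pde4b and Pde4d rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0381, adjusted p = 0.426 with an estimated correlation). Vegfa was the 1 of 18 glycolysis and hypoxia genes that rose and Per1 the 1 of 12 circadian clock genes, by both adjustments (camera adjusted p = 0.0119 and 0.0252, each adjusted p = 0.426 with an estimated correlation).

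**Figure D2:**
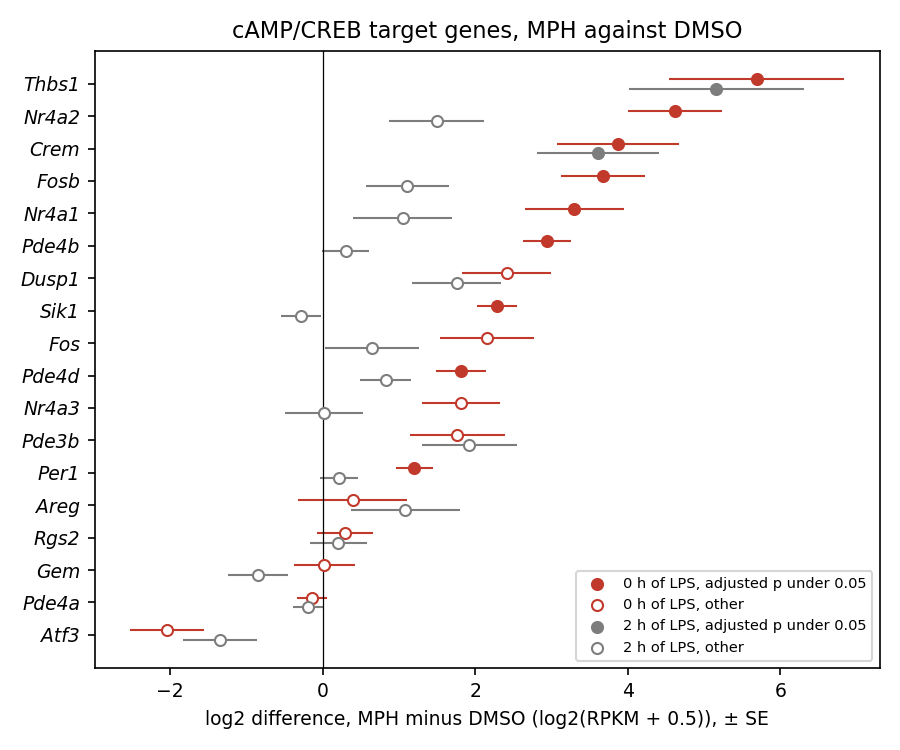
Log2 difference between MPH and DMSO for the 18 cAMP/CREB target genes at 0 h (red) and 2 h (grey) of LPS, with bars of 1 SE and filled points for adjusted p under 0.05. At 0 h 9 genes are filled, from Per1 at 1.20 to Thbs1 at 5.69, and at 2 h Crem at 3.61 and Thbs1 at 5.16.

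At 0 h Cd14, which encodes a co-receptor for LPS, rose from 36.2 ± 5.0 to 193 ± 23.9 RPKM, or 2.40 (SE 0.26, adjusted p = 8.25e-05), the 1 of 20 Toll-like receptor pathway genes and of 16 macrophage identity genes to pass by either adjustment. Osm, which encodes the cytokine oncostatin M, rose by 2.80 (adjusted p = 0.0357), 1 of 17 inflammatory cytokine genes, with 2 higher and 1 lower adjusted over the list alone. Il1r2, which encodes a decoy receptor for interleukin-1, rose by 2.36 (adjusted p = 0.0498, not past the threshold after median-of-ratios scaling), 1 of 14 genes of the IL-1 family list by either adjustment. Of 14 chemokine genes Ccl3 fell and 13 did not pass, with 1 higher and 2 lower adjusted over the list alone. The camera adjusted p of these lists lay between 0.153 for cytokines and 0.99 for the Toll-like receptor pathway, with 0.35 for the IL-1 family, 0.238 for chemokines and 0.473 for macrophage identity genes. The mean of the IL-1 family, cytokine and macrophage identity lists was above 0 where the median was below. Interferon-stimulated (27 genes), LXR target (9), heat-shock and stress (15) and dendritic cell (4) lists had no member past the threshold by either adjustment (limma) and camera adjusted p of 0.99, 0.454, 0.99 and 0.166. The median (-0.13) and mean of the interferon-stimulated genes were below 0 where camera put the list above other genes. No member passed by either adjustment among 17 cholesterol biosynthesis genes, 18 cell cycle genes or 10 neutrophil markers (limma). As a list the cholesterol genes were lower (median -0.36, camera adjusted p = 0.00152, adjusted p = 0.507 with an estimated correlation). So were the cell cycle genes (median -0.34, camera adjusted p = 0.000326, adjusted p = 0.507 with an estimated correlation). The neutrophil markers were higher (median 0.59, camera adjusted p = 0.00795, adjusted p = 0.426 with an estimated correlation). The neutrophil gene S100a8 was at 18 ± 4.57 RPKM with MPH and 10.4 ± 6.09 RPKM with DMSO (adjusted p = 0.887).

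At 1 h of LPS the MPH cultures did not form a uniform group. Over the 69 genes higher with MPH at 0 h, the libraries of M2 and M3 lay on average 1.35 and 1.23 above D3 to D6 on the log2 scale at 1 h. The library labelled M4 lay 0.02 above, within the range of D3 to D6 (-0.14 to 0.12). The M4 libraries of 0 and 2 h stood at 1.83 and 0.66 over these genes, outside the ranges of the DMSO libraries. The genes had been chosen from the 0 h libraries, so the 0 h values are not free of that choice. The 1 and 2 h values come from other libraries of the same cultures, which deviate together, and are not fully independent of it. Limma called 0 of 10239 genes for MPH against DMSO at 1 h with all 3 cultures, with 327 at unadjusted p below 0.05 and 152 whose groups did not overlap (1.48%, against 5.71% by chance). The smallest p, none past the threshold, belonged to Uck2 (1.38), Auh (0.74), Dgat1 (1.37), Zcchc14 (0.54) and Grasp (0.76), each with adjusted p = 1. In the list tests the cAMP/CREB targets (camera adjusted p = 7.54e-10), regulatory macrophage genes (1.52e-05) and glycolysis and hypoxia genes (0.00158) were higher, with adjusted p = 0.0912, 0.0912 and 0.411 with an estimated correlation. Fry called none of these (fry adjusted p = 0.19, 0.19 and 0.61). Adjusted over the list alone 6, 3 and 1 members of these were higher. Against all 7 DMSO cultures 4 genes passed with a covariate and 1 without, and 112 passed when the whole culture M4 was left out.

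**Figure D3:**
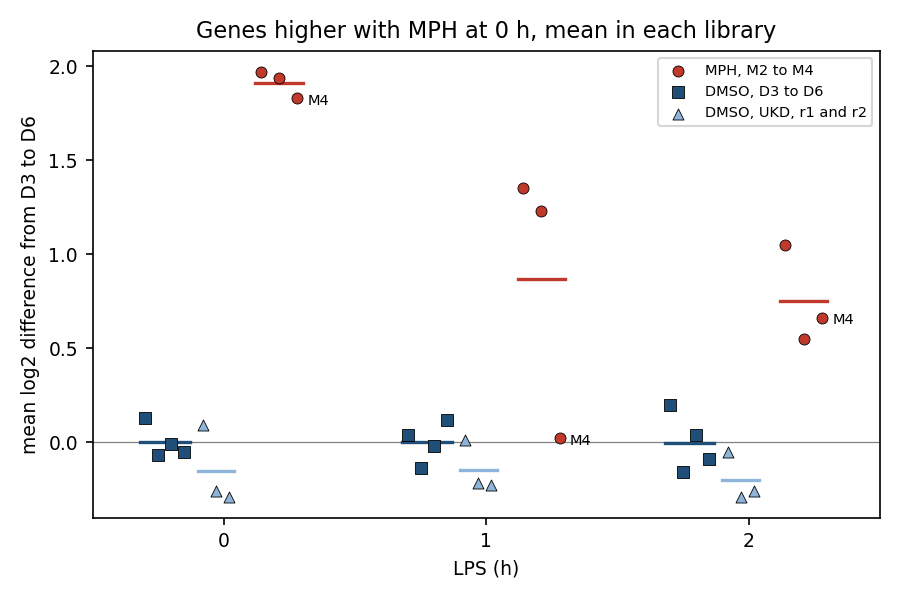
Mean log2 difference from D3 to D6 over the 69 genes higher with MPH at 0 h, for each library against hours of LPS, with squares and triangles for DMSO, circles for MPH and lines for group means. The 1 h library labelled M4 lies at 0.02, among the DMSO libraries, and the other MPH libraries lie between 0.55 and 1.97.

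Without that library, a choice made after the values were seen, 137 genes passed at 1 h, 90 higher and 47 lower, among 10231 tested, with 983 at unadjusted p below 0.05. With 2 against 4 cultures, 1488 genes did not overlap (14.5%, against 13.3% by chance). Thbs1 was at 499 RPKM on average (372 and 626) against 11.8 ± 10.1, a log2 difference of 5.70 (SE 0.68, adjusted p = 0.000309). Il10, the gene of an anti-inflammatory cytokine, was at 39.8 RPKM (29.2 and 50.4) against 1.78 ± 1.43, or 4.33 (SE 0.47, adjusted p = 0.000102). Il6, the gene of a pro-inflammatory cytokine, was at 57.8 RPKM (38.6 and 77.1) against 9.14 ± 8.83, or 2.96 (SE 0.55, adjusted p = 0.00862). Cytip (4.32), Crem (4.19), Nr4a2 (3.36), Hilpda (3.35), Trem1 (2.90), Il1r2 (2.79) and Dusp14 (2.79) rose as well. The largest fall was that of Atf3, a stress-induced transcription factor gene, from 120 ± 41.4 to 27.4 RPKM (25.3 and 29.6), or -2.06 (SE 0.36). Other falls were those of Prag1 (-1.98), Rasgrp3 (-1.89), S1pr2 (-1.87), Plekhm1 (-1.61), Nav2 (-1.42), Ticam1 (-1.41), Tec (-1.39) and Slc15a4 (-1.33). Of 17 inflammatory cytokine genes 5 rose, Il10, Ptgs2 (2.21), Il6, Osm (2.70) and Il1a (2.10), and 12 did not pass. There were 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00148, adjusted p = 0.559 with an estimated correlation). Of 13 regulatory macrophage genes Il10, Thbs1, Odc1 (2.62) and Vegfa (2.76) rose, with 6 higher adjusted over the list alone (camera adjusted p = 1.06e-07, adjusted p = 0.0106 with an estimated correlation). Of 18 cAMP/CREB targets 6 rose, among them Pde4d (1.65) and Fosb (2.66), and Atf3 fell. There were 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.5e-12, adjusted p = 0.0106 with an estimated correlation). Il1b itself did not pass (1.76, SE 0.66, adjusted p = 0.341). Il1r2 and Il1a were the 2 of 14 IL-1 family genes that rose, with 3 higher adjusted over the list alone (camera adjusted p = 0.000936, adjusted p = 0.581 with an estimated correlation). Cholesterol biosynthesis genes were lower as a list (median -0.38, camera adjusted p = 0.00141, adjusted p = 0.827 with an estimated correlation). The count was 62 when the 1 h libraries of D4 and D6 were left out as well.

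At 2 h of LPS, MPH again went with high Thbs1, at 316 ± 129 RPKM against 8.57 ± 4.39, a log2 difference of 5.16 (SE 1.15, adjusted p = 0.0365). Crem was higher by 3.61 (SE 0.80), the phosphatase gene Dusp14 by 3.39 (SE 0.53) and Odc1, which encodes the first enzyme of polyamine synthesis, by 2.41 (SE 0.52), from 19.3 ± 3.60 to 106 ± 25.1 RPKM. Cd14 reached 999 ± 168 RPKM against 414 ± 82.1 (1.28, SE 0.26, adjusted p = 0.0258). Nav2 (-1.83, SE 0.34) and Fgd3 (-1.49, SE 0.25) were the most reduced, and Vav1, which encodes a guanine nucleotide exchange factor, fell from 30.2 ± 3.33 to 15 ± 2.58 RPKM (-0.99, SE 0.21). Further rises were those of Gng4 (2.72), Plet1 (2.58), U90926 (2.56), Rnd1 (2.42), Mxi1 (2.18) and Pitpnc1 (2.08). Further falls were those of Tbc1d1 (-1.37), Zc3h12c (-1.26), Swap70 (-1.24), the potassium channel gene Kcnk13 (-1.20), Stk38l (-1.18), the cell cycle kinase gene Cdk6 (-1.15) and Cd180 (-1.10), which encodes a homologue of Toll-like receptors. Past the threshold were 89 of 10239 genes (limma), 49 higher and 40 lower, with 930 at unadjusted p below 0.05 and 41 changed at least 2-fold. The groups did not overlap in 973 genes (9.50%, against 5.71% by chance). Of 23 named calls none held in all 7 removals of a culture, Plet1 being untested in the 3 that left out an MPH culture and called in the other 4. The count was 41, 3 and 21 without the 2 h libraries of M2, M3 and M4, and 27, 35 and 40 without those of D4, D5 and D6. It was 215 without the 1 h library labelled M4 and 2, 2, 26, 27 and 1 without the whole cultures D4, D5, D6, M2 and M3. Against all 7 DMSO cultures it was 405 with a covariate and 335 without, and with the 2 h libraries alone 23.

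By list, Il4ra (1.72), a receptor gene for interleukin-4, Odc1 and Thbs1 rose among 13 regulatory macrophage genes at 2 h and 10 did not pass. There were 6 higher adjusted over the list alone (camera adjusted p = 1.07e-07, adjusted p = 0.0495 with an estimated correlation, or 0.0565 after median-of-ratios scaling, fry adjusted p = 0.0111). Of 18 cAMP/CREB targets Crem and Thbs1 rose and 16 did not pass, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00115, adjusted p = 0.507 with an estimated correlation). Cd14 and Irak3 (0.74), an inhibitor of Toll-like receptor signalling, were the 2 of 20 genes of that pathway to rise by either adjustment (camera adjusted p = 0.309). No gene of the IL-1 family list passed (limma), but 2 of 14 were higher after median-of-ratios scaling, as were 2 adjusted over the list alone (camera adjusted p = 0.0455, adjusted p = 0.788 with an estimated correlation). Glycolysis and hypoxia genes were higher as a list, with a median of 0.22 and 0 members past the threshold (limma, camera adjusted p = 0.00115, adjusted p = 0.507 with an estimated correlation). Cholesterol biosynthesis and cell cycle genes were lower, with medians of -0.27 and -0.22 and 0 members past the threshold (limma, camera adjusted p = 0.0455 for both, adjusted p = 0.788 with an estimated correlation). Of the genes higher at 0 h, 7 of 69 were also called higher at 2 h (Cnnm2, Crem, Thbs1, Cd14, Dgat1, Gpn3 and Uck2), where independent lists share 0.33, and 0 of the lower genes were called lower at both times. The cultures are the same at both times, and the split of D4, D6 and M3 against the other 4 cultures shared 363 higher genes.

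The LPS response at 2 h differed by treatment for 11 of 10239 genes (limma), 9 with a lower log2 change under MPH and 2 with a higher one. Pde4b went from 11.3 ± 4.80 to 49.0 ± 5.45 RPKM with MPH and from 1.02 ± 0.618 to 39.8 ± 4.57 RPKM with DMSO, an interaction of -2.64 (SE 0.44, adjusted p = 0.0251). Sik1 went from 9.75 ± 1.71 to 0.382 ± 0.215 RPKM with MPH and from 1.65 ± 0.622 to 0.555 ± 0.0849 RPKM with DMSO, an interaction of -2.57 (SE 0.37, adjusted p = 0.00624). Zfp36 (-2.10), the anti-proliferative gene Btg2 (-1.998), the kinase gene Nuak2 (-1.87), Grasp (-1.54), Cdkn1a (-1.51), which encodes the cell cycle inhibitor p21, Zcchc14 (-1.50) and Hs6st1 (-1.02) had negative interactions, and Plet1 (2.56) and Cdyl (0.98) positive ones. Pde4b, Sik1, Zfp36, Btg2, Nuak2, Grasp, Cdkn1a and Zcchc14 were also among the genes higher with MPH at 0 h. Both comparisons use the same 0 h libraries, so part of that overlap may come from the shared libraries. A negative interaction need not mean a lower level after LPS. At 2 h Btg2 was at 5.74 RPKM with MPH and 5.64 RPKM with DMSO, Nuak2 at 2.25 and 2.285 and Zcchc14 at 0.307 and 0.323. Cdkn1a (171 and 253 RPKM) and Hs6st1 (3.405 and 6.18 RPKM) were lower with MPH at 2 h. Of 18 cAMP/CREB targets Pde4b and Sik1 were lower, with 5 lower adjusted over the list alone (camera adjusted p = 1.13e-13, adjusted p = 0.031 with an estimated correlation, or 0.0706 after median-of-ratios scaling, fry adjusted p = 0.173). Of 20 NF-kB genes Zfp36 was lower, with 2 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00251, adjusted p = 0.905 with an estimated correlation). The count was 5, 3, 7, 3 and 4 without the 2 h libraries of D4, D5, M2, M3 and M4. It was 6, 5, 3, 7, 4, 5 and 6 without the 0 h libraries of D3, D4, D5, D6, M2, M3 and M4, and 7 without the 1 h library of M3. Without a whole culture it was 4, 4, 1, 6, 5, 0 and 4 (D3, D4, D5, D6, M2, M3 and M4). None of the 11 calls held in every removal of a culture. With the culture as a block 146 genes passed, 78 higher and 68 lower, the 11 among them. MAPK genes were then lower as a list (camera adjusted p = 0.0312, adjusted p = 0.891 with an estimated correlation) and the cAMP/CREB call had adjusted p = 0.288 with an estimated correlation.

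At 1 h limma called 0 genes for a different LPS response, with 83 at unadjusted p below 0.05. The smallest p belonged to Nuak2 (-1.66, adjusted p = 0.0648), Pde4b (-2.48, adjusted p = 0.128), Btg2 (-1.97, adjusted p = 0.128), Sik1 (-1.97, adjusted p = 0.128) and Zcchc14 (-0.93, adjusted p = 0.149). The cAMP/CREB list was lower, with a median of -1.15 and 2 of 18 lower adjusted over the list alone (camera adjusted p = 1.56e-19, adjusted p = 0.00662 with an estimated correlation, or 0.341 without the 1 h library labelled M4 and 0.1 with the culture as a block). Fry did not call it (fry adjusted p = 0.42). NF-kB genes (median -0.32, camera adjusted p = 2.81e-08), regulatory macrophage genes (-0.25, 0.0241), MAPK genes (-0.00, 0.0241) and neutrophil markers (-0.25, 0.00939) were lower as lists and cell cycle genes (0.32, 0.000279) higher. With an estimated correlation these had adjusted p = 0.203, 0.456, 0.498, 0.412 and 0.544. After median-of-ratios scaling the regulatory and MAPK lists had camera adjusted p = 0.0951 and 0.0997. With the culture as a block 20 genes passed, 5 higher and 15 lower, among them Nuak2 (adjusted p = 0.00652), Pde4b (0.000671), Sik1 (0.00845) and Zcchc14 (0.0128). Without single libraries the count was 1 (D4 or D6 at 0 h, D6 or M4 at 1 h, D3 at 2 h) or 2 (M4 at 0 h), and without a whole culture 1 (D3) or 3 (M4).

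LPS alone, in the 7 DMSO cultures, raised genes of inflammatory signalling within 1 h. Tnf, a central inflammatory cytokine gene, rose from 11.4 ± 4.90 to 2070 ± 397 RPKM (7.53, SE 0.25, adjusted p = 1.3e-14). Il1b rose from 0.480 ± 0.587 to 271 ± 131 RPKM (8.14, SE 0.31) and reached 547 ± 144 RPKM at 2 h (9.26, SE 0.31). The chemokine genes Cxcl2 (9.20), Cxcl1 (8.44) and Cxcl10 (6.77) and the NF-kB regulators Nfkbiz (7.19) and Tnfaip3 (5.85) rose at 1 h, with Socs3 (6.76), Tnfsf9 (6.41) and Il1a (6.20). At 2 h Cxcl10 (8.50), Il12b (7.54), Acod1 (7.31), which encodes the enzyme that makes itaconate, and Cxcl3 (6.70) were among the largest rises. Falls at 1 h were led by Txnip, a regulator of glucose uptake (-3.11, SE 0.31), and Gm15441 (-2.22), which overlaps Txnip on the other strand and is uncertain for that reason. They included Id1 (-1.88), Rhov (-1.81), AI467606 (-1.61), Cd300lb (-1.54), Tsc22d3 (-1.50), Arrdc3 (-1.48), Dusp6 (-1.47) and the pseudogene Hmga2-ps1 (-1.46). At 2 h Cd300lb (-3.21), Hhex (-3.16), Dusp6 (-2.95), Txnip (-2.82), Cnr2 (-2.73), Rhov (-2.64), Arhgap25 (-2.63), Cxcr4 (-2.57) and Zfp36l2 (-2.56) were among the genes that fell most.

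Limma called 2071 of 10212 genes at 1 h, 535 higher and 1536 lower, and 5529 at 2 h, 1075 higher and 4454 lower. The median change of all genes was -0.15 at 1 h and -0.25 at 2 h, a shift that median-of-ratios scaling brought to -0.01 and -0.02. Relative to it, 684 genes were higher and 522 lower at 1 h, and 1813 higher and 1970 lower at 2 h. Quantile normalization gave 611 higher and 760 lower, and 1446 higher and 2516 lower. Among changes of at least 2-fold, 294 were higher and 55 lower at 1 h and 510 higher and 418 lower at 2 h as deposited, against 324 and 30, and 633 and 218, after median-of-ratios scaling. With the culture as a block 5459 genes passed at 1 h, 889 higher and 4570 lower. The 1 h count was 1237 without r1, 1198 without the 3 libraries below 10 M reads, 4346 with library weights, 1333 without the covariate and 406 with D3 to D6 alone, for which the 2 h count was 2490.

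All 20 NF-kB feedback and family genes rose at both times under DMSO, among them Nfkbia (4.80 at 1 h), Zfp36 (4.71 at 1 h) and Zc3h12a (3.71 at 2 h). Of 17 inflammatory cytokine genes 15 rose at 1 h and 17 at 2 h, and of 15 chemokine genes 13 and 15, with 16 and 15 at 1 h adjusted over the list alone. These 3 lists were higher at both times, with camera adjusted p of at most 2.18e-24 and adjusted p of at most 0.00246 with an estimated correlation. Ptgs2, which encodes a prostaglandin synthase, rose by 5.81 and 6.70. Of 20 MAPK genes 16 rose and 1 fell at 1 h, among them Egr2 (5.23), Dusp2 (4.46) and Phlda1 (4.07), and at 2 h 12 rose and 5 fell, or 13 and 5 adjusted over the list alone. As a list they were higher (camera adjusted p = 1.12e-27 and 9.81e-07, adjusted p = 0.00052 and 0.0962 with an estimated correlation). Of 13 IL-1 family genes 5 rose at 1 h and 5 rose and 2 fell at 2 h, led by Il1b, Il1a, Nlrp3 (4.41 at 2 h), the sensor of an inflammasome, and Il1rn (2.56 at 2 h). At 1 h 1 was lower adjusted over the list alone, and the list was higher (camera adjusted p = 4.91e-10 and 7.23e-07, adjusted p = 0.0092 and 0.0492 with an estimated correlation, the second 0.0884 after median-of-ratios scaling). Of 13 regulatory macrophage genes 6 rose at each time and 1 fell at 2 h, among them Lif (3.24 at 1 h) and Il10 (2.35 at 2 h). At 2 h 7 were higher adjusted over the list alone, and the list was higher (camera adjusted p = 1.92e-10 and 9.81e-07, adjusted p = 0.000256 and 0.00246 with an estimated correlation). Of 15 cAMP/CREB targets 7 rose and 3 fell at 1 h, and 6 rose and 5 fell at 2 h, by either adjustment. Pde4b rose by 4.97 and 4.83 and Rgs2 changed by -2.43 at 2 h, and the list was higher (camera adjusted p = 1.22e-08 and 0.0177, the second 0.306 after median-of-ratios scaling, adjusted p = 0.00143 and 0.144 with an estimated correlation). Of 27 interferon-stimulated genes 9 rose at 1 h and 15 at 2 h, among them Irf1 (4.07 at 1 h) and Gbp5 (6.11 at 2 h). At 1 h 10 were higher adjusted over the list alone, and the list was higher (camera adjusted p = 3.85e-09 and 8.67e-15, adjusted p = 0.263 and 0.14 with an estimated correlation).

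Of 20 Toll-like receptor pathway genes 5 rose and 1 fell at 1 h and 7 rose and 4 fell at 2 h, with Cd14 (3.41) and Tlr2 (3.91) the largest at 2 h. At 2 h 8 were higher adjusted over the list alone, and the list was higher (camera adjusted p = 0.000898 and 6.85e-05, adjusted p = 0.129 and 0.0931 with an estimated correlation, or 0.0349 and 0.0261 with the culture as a block). Of 20 adrenergic and cAMP machinery genes 1 rose and 2 fell at 1 h and 2 rose and 11 fell at 2 h, among them Arrb1 (-0.96), Rapgef3 (-0.88) and Pde4a (-0.73) at 2 h (camera adjusted p = 0.487 and 0.615). Adjusted over the list alone 1 rose and 0 fell at 1 h, and after median-of-ratios scaling 2 rose and 6 fell at 2 h. Of 18 glycolysis and hypoxia genes 2 rose at 1 h, Acod1 (5.54) and Ero1a (0.34), and 5 rose and 1 fell at 2 h, by either adjustment. Camera put the list above other genes, with medians of -0.12 at both times where means were above 0 (camera adjusted p = 0.0134 and 0.0126, adjusted p = 0.357 and 0.39 with an estimated correlation, and 0.0519 at 1 h with the culture as a block). Only 6 of 18 members had a positive change at each time. Acod1 rose most (5.54 and 7.31), and the list was not tested without it. Of 18 cell cycle genes 0 passed at 1 h and 11 fell at 2 h, including Cdc20 (-0.64), Plk1 (-0.75), Mcm6 (-0.59) and Birc5 (-0.53). After median-of-ratios scaling 2 fell and 1 rose at 2 h (limma, camera adjusted p = 0.845 and 0.286, and 0.0109 at 2 h with the culture as a block, where adjusted p = 0.361 with an estimated correlation). Of 12 circadian clock genes Cry2 (-0.53) fell at 1 h and 6 fell at 2 h, among them Per1 (-1.19) and Bhlhe41 (-1.41), against 5 lower and 2 higher after median-of-ratios scaling (camera adjusted p = 0.487 and 0.505). Of 17 cholesterol biosynthesis genes Insig1 (1.01) rose at 1 h and 4, led by Dhcr7 (-0.80), fell at 2 h, against 3 higher and 2 lower after median-of-ratios scaling. The list did not pass (camera adjusted p = 0.0787 and 0.672, and 0.0126 at 1 h with the culture as a block, where adjusted p = 0.273 with an estimated correlation). Of 9 LXR targets 0 passed at 1 h, and at 2 h the cholesterol transporter genes Abca1 (1.14) rose and Abcg1 (-1.04) fell, as did Scd2 (-1.24) and Mylip (-0.57). After median-of-ratios scaling 1 rose and 2 fell (limma, camera adjusted p = 0.487 and 0.696).

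Of 15 heat-shock and stress genes Gadd45b (3.37), Gadd45a (1.28), Hspa1a (1.44) and Hspa1b (1.14) rose at 1 h and 1 fell, or 2 adjusted over the list alone, with uncertain values for the near-identical Hspa1a and Hspa1b. At 2 h 3 rose and 5 fell, or 4 and 2 after median-of-ratios scaling. The list was higher at 1 h (camera adjusted p = 0.00907 and 0.172, adjusted p = 0.103 at 1 h with an estimated correlation, or 0.0449 with the culture as a block). Of 16 macrophage identity genes Cd14 rose and 2, among them Fcgr3 (-0.22), fell at 1 h, and 2 rose and 4 fell at 2 h, with 3 lower adjusted over the list alone and 2 and 2 after median-of-ratios scaling (camera adjusted p = 0.266 and 0.551). No neutrophil (8) or dendritic cell (4) marker passed at either time (limma). The neutrophil markers were higher as a list at 1 h (median 0.57, camera adjusted p = 0.00907, or 0.0509 after median-of-ratios scaling, adjusted p = 0.263 with an estimated correlation) and at 2 h had camera adjusted p = 0.0505. The dendritic cell markers had camera adjusted p = 0.27 and 0.19. With the culture as a block the neutrophil markers had adjusted p = 6.83e-05 and 0.00397 and 5 members higher at each time, with 1 lower at 2 h. The dendritic cell markers then had 0.0126 and 0.0129 and 2 members higher at each time. With an estimated correlation these block values were 0.0449 and 0.146, and 0.0421 and 0.0539. In the heat-shock list the median was -0.04 at 1 h and -0.24 at 2 h where the mean and test were above 0. The cholesterol, LXR target and macrophage identity lists had medians and means of at most -0.16 at 2 h where camera put them above other genes, whose median was lower. The B cell marker Cd79b fell by 0.57 at 2 h, from 0.892 to 0.454 RPKM (adjusted p = 0.00123).

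The LPS response was also tested in the 3 MPH cultures, the 1 h library labelled M4 included. Cxcl2 (9.36), Cxcl1 (8.80), Tnf (8.55, SE 0.48), Il1a (7.36), Il1b (7.17, SE 0.72), Nfkbiz (6.86), Ccl3 (6.65), Ccl4 (6.59), Tnfaip3 (6.46) and Tnfsf9 (6.46) rose most at 1 h. The largest rises at 2 h were those of Il1a (9.24), Il1b (9.11, SE 0.72), Cxcl2 (8.70), Cxcl1 (7.96), Cxcl10 (7.83), Ccl4 (7.80), Acod1 (7.68), Ccl3 (7.60), Tnf (7.52) and Cxcl3 (6.91). Txnip (-2.63), Sik1 (-2.50), Tsc22d3 (-2.06), Sertad3 (-1.74), Rhov (-1.70), Thbd (-1.68), Gm15441 (-1.57), Phf13 (-1.54), Armc7 (-1.42) and Gna11 (-1.40) fell at 1 h. At 2 h Sik1 (-3.55), Fos (-3.46), Thbd (-3.34), Cd300lb (-3.32), Nr4a2 (-3.11), Lpar6 (-2.93), Tsc22d3 (-2.93), Klf4 (-2.91), Arrdc3 (-2.91) and Nuak2 (-2.81) fell. Limma called 315 genes at 1 h, 194 higher and 121 lower, and 2121 at 2 h, 611 higher and 1510 lower, or 214 and 73 at 1 h and 819 and 593 at 2 h after median-of-ratios scaling. Quantile normalization gave 201 higher and 68 lower at 1 h and 692 higher and 630 lower at 2 h. With the culture as a block 1236 genes passed at 1 h, 477 higher and 759 lower, and 5577 at 2 h, 1195 higher and 4382 lower. Without the 1 h library labelled M4 the 1 h count was 322, 205 higher and 117 lower, with 256 of the 315 among them, and Thbd did not pass. The 1 h count was 198 without the 0 h library labelled M4, and the 2 h count was 1313 without the 2 h library of M4. Without the whole cultures M2, M3 and M4 the 1 h count was 147, 182 and 178, and without M3 and M4 the 2 h count was 819 and 882. Of 46 named calls at 1 h 29 held when each culture was left out in turn, and of 62 at 2 h 48 held. The calls of Armc7, Gm15441, Thbd and Il10 at 1 h held in 2, 3, 1 and 3 of the 7 cases. Of the genes called higher under MPH, 187 of 192 at 1 h and 552 of 600 at 2 h were also called higher under DMSO, where independent lists share 10.1 and 63.5. Of those called lower, 107 of 111 and 1418 of 1491 were lower in both, against 16.7 and 651.

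By list under MPH, 14 and 18 of 20 NF-kB genes rose at 1 and 2 h, 12 and 15 of 17 inflammatory cytokine genes and 8 and 11 of 14 chemokine genes. Adjusted over the list alone these were 16 and 18, 13 and 16, and 10 and 12. These 3 lists were higher at both times, with camera adjusted p of at most 4.34e-23 and adjusted p of at most 0.0049 with an estimated correlation. Of 20 MAPK genes 9 rose at 1 h, including Egr1 (5.80) and Egr2 (5.41), and 6 rose and 3 fell at 2 h, with 12 and 1, and 7 and 4, adjusted over the list alone. The list was higher (camera adjusted p = 2.22e-20 and 0.000212, adjusted p = 0.00119 and 0.181 with an estimated correlation). Of 14 IL-1 family genes 5 rose at each time, among them Nlrp3 (3.72 and 4.34), with 5 at 1 h and 6 higher and 1 lower at 2 h adjusted over the list alone. The list was higher (camera adjusted p = 1.79e-11 and 7.66e-08, adjusted p = 0.0465 and 0.113 with an estimated correlation, the second 0.0316 with the culture as a block). Of 13 regulatory macrophage genes 4 rose at each time by either adjustment, Socs3, Lif, Il1rn and Il10 (5.58 at 2 h), and 1 fell at 2 h. The list was higher (camera adjusted p = 2.88e-05 and 1.02e-05, adjusted p = 0.0498 and 0.0436 with an estimated correlation, or 0.0998 and 0.121 after median-of-ratios scaling and 0.212 and 0.126 with the culture as a block). Of 18 cAMP/CREB targets 5 rose and 1, Sik1, fell at 1 h, and 3 rose and 8 fell at 2 h, among them Per1 (-1.99), with 5 and 4, and 4 and 9, adjusted over the list alone. The list did not pass (camera adjusted p = 0.345 and 0.713), and at 1 h its median was -0.30 where its mean and test were above 0. Of 27 interferon-stimulated genes 3 and 10 rose by either adjustment (camera adjusted p = 2.88e-05 and 1.23e-09, adjusted p = 0.554 and 0.295 with an estimated correlation). Of 20 Toll-like receptor pathway genes 3 and 6 rose by either adjustment, with Tlr2 at 2.37 and 3.15 (camera adjusted p = 0.00283 and 1.25e-05, adjusted p = 0.141 and 0.0436 with an estimated correlation, the first 0.0427 with the culture as a block and the second 0.069 after median-of-ratios scaling). Without the 1 h library labelled M4, 7 MAPK genes and 4 cAMP/CREB targets rose at 1 h and the other counts of this paragraph at 1 h past the threshold were the same. The cAMP/CREB list was then higher at 1 h (camera adjusted p = 0.00885, adjusted p = 0.276 with an estimated correlation).

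Of 20 adrenergic and cAMP machinery genes 2, among them Pde4b, rose at 1 h, and 2 rose and 5 fell at 2 h, with 2 and 1, and 2 and 6, adjusted over the list alone (camera adjusted p = 0.705 and 0.713). Of 18 glycolysis and hypoxia genes 1 rose at 1 h and 4 rose and 1 fell at 2 h by either adjustment, with Acod1 the largest. Camera put that list above other genes, with medians of -0.00 and -0.01 where means were above 0 (camera adjusted p = 0.0218 and 0.00288, adjusted p = 0.4 and 0.242 with an estimated correlation). Of its 18 members 9 and 8 had a positive change, and it was not tested without Acod1. Of 15 heat-shock and stress genes 3 rose at 1 h and 4 rose and 1 fell at 2 h, with 2 lower at 2 h adjusted over the list alone (camera adjusted p = 0.00226 and 0.127, adjusted p = 0.0873 at 1 h with an estimated correlation). Cholesterol biosynthesis (median 0.18) and cell cycle genes (median 0.10) were higher as lists at 1 h with 0 members past the threshold (limma, camera adjusted p = 0.0291 and 0.0341, adjusted p = 0.694 for both with an estimated correlation). Without the 1 h library labelled M4 these 2 lists and the glycolysis and hypoxia genes did not pass at 1 h (camera adjusted p = 0.925, 0.122 and 0.206). With the culture as a block the neutrophil and dendritic cell markers had camera adjusted p = 0.0162 and 0.0304 at 1 h, against 0.25 and 0.464 without it, and the dendritic cell markers 0.00912 at 2 h, against 0.268. With an estimated correlation these block values were 0.169, 0.124 and 0.0681.

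Genes that responded to LPS in the UKD, r1 and r2 cultures, which share no library with the comparisons of MPH, were followed under MPH. Of the 200 that rose most at 1 h there, 19 were higher with MPH before LPS, such as Pde4b and Osm, 4 were lower, including Ccl3, and 177 did not pass, with 35 and 14 adjusted over the list alone. The list was higher (median 0.07, camera adjusted p = 4.41e-06, adjusted p = 0.388 with an estimated correlation, fry adjusted p = 0.476), and its genes changed in both directions (fry mixed adjusted p = 1.67e-08). At 2 h of LPS 3 of them were higher and 1 lower with MPH, and the list as a whole did not differ (median -0.02, camera adjusted p = 0.751). The LPS response of these 200 genes at 1 h was lower under MPH, with a median interaction of -0.28 (camera adjusted p = 1.69e-14, adjusted p = 0.0483 with an estimated correlation, or 0.516 without the 1 h library labelled M4), and 0 genes passed singly (limma). Fry did not call the list there (fry adjusted p = 0.436).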

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

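The library at 1 h labelled M4 was tested against explanations chosen only after its values were seen, as were those for pairs of cultures, whereas the splits of the samples and the tests of the excess of falls after LPS were set beforehand. Its mean over the 69 genes higher with MPH at 0 h was 0.02, where M2 and M3 stood at 1.35 and 1.23. Cells that received no MPH, or a wrong label, could give such a value and its correlation with D5 at 1 h over expressed genes (0.9944), the highest of all pairs of libraries, where M2 with D3 and M3 with the shallow D4 stood at 0.98 and 0.9717 at 1 h. A swap with a DMSO library of the same time would leave a DMSO library high, but the highest of the 7 was at 0.12. Low depth is argued against by its 44 M reads, against 27.1 M for M3 at 1 h, and a weak response of culture M4 by its value of 0.66 at 2 h, where M3 stood at 0.55.

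Deviations from the group means ran together between certain DMSO and MPH cultures. The pairs D3 with M2, D4 with M3 and D5 with M4 had correlations between 0.741 and 0.906 over 9 pairs of libraries, and each of the 9 MPH libraries was closest to that DMSO library at its time. D4 and M3 were the only 2 cultures with Xist, expressed from the inactive X chromosome, above the Y-linked Ddx3y. A shared animal or preparation may therefore link these pairs, which the titles do not state. The numbers in the titles do not give the link, because D and M libraries of the same number had correlations of at most -0.358. Certain DMSO cultures were as close to each other. Over expressed genes at 0 h r1 with r2 correlated at 0.9885, UKD with D5 at 0.9864 and D5 with D6 at 0.9775. On that scale D3 with M2, D4 with M3 and D5 with M4 stood at 0.9816, 0.9743 and 0.9804. UKD, r1 and r2 may thus not be 3 separate units, nor UKD be separate from D5.

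More genes fell than rose after LPS in the DMSO cultures, by a median of -0.25 at 2 h. The genes higher at 2 h took 8.66% of approximate reads at 0 h and 23.8% at 2 h, which shifts the summed share of all others by -0.26 ± 0.05 (SD, n = 7) on the log2 scale. Shares sum to 1 and these genes were chosen because they were higher, so the value follows with or without a loss of transcripts per cell. Reads taken by induced genes and transcripts lost per cell cannot be told apart here, since no measure of RNA per cell was given. Noise of low values does not account for all of it, since 68.1% of the 1666 genes called at 2 h with a mean of at least 10 RPKM were lower. Over all 5529 calls the share was larger, with 4454 lower and 19.4% higher, so a part from low values is not excluded.

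Other groupings of the cultures were called in the same way. For MPH against DMSO at 0 h, 3 of 35 splits reached the real count of 89, and the highest other split gave 1719, so these free splits do not exclude chance. At 2 h 4 of 35 splits reached 89, with 974 in the highest other, so they do not exclude it there. At 1 h the real count was 0, which all 35 splits reach whatever the data, so that comparison tests nothing, and the highest other split gave 2482. Some splits call several times the real count and point to a structure of the samples: D5, D6 and M4 against the rest gave 1719 and 2482 genes at 0 and 1 h, and D4, D6 and M3 gave 974 at 2 h. Each of these 2 splits keeps D3 with M2, D4 with M3 and D5 with M4 together, so the cultures may not be interchangeable as the free splits assume. The pairs do not account for every split, since D3, D6 and M2, which also keeps all 3 together, gave 0, 11 and 0 genes at 0, 1 and 2 h. D3, M2 and M3, which parts D4 from M3, gave 1481 at 1 h, and D3, M2 and M4, which parts D5 from M4, gave 112 at 2 h. Of the 8 splits that part all 3 pairs, a comparison chosen only after the result was seen, the real one gave 89 and the highest other 0, at 0 h and at 2 h. Those 8 are too few for a share below 0.05, and no model with such pairs was run, because they were found from the data. For the difference in LPS response at 2 h, 1 of 35 splits, the real one, reached 11, with 3 in the highest other, so chance is excluded only if the cultures are interchangeable. Of the 8 splits that part all 3 pairs the real one gave 11 and the highest other 0, again too few for a share below 0.05. At 1 h the real count was 0, as was the highest other, and all 35 splits reach 0 whatever the data, so that comparison tests nothing. For LPS in DMSO, 1 of 100 splits reached 2071 at 1 h (highest other 943) and 1 of 100 reached 5529 at 2 h (highest other 3191). Chance is thus excluded only if the libraries are interchangeable, and those of 1 culture deviated together. For LPS in MPH, 1 of 10 splits reached 315 at 1 h and 1 of 10 reached 2121 at 2 h, with 0 in the highest other for both, and 10 splits are too few for a share below 0.05. Of the genes called higher and lower under MPH, 187 of 192 and 107 of 111 at 1 h, and 552 of 600 and 1418 of 1491 at 2 h, were called in the same direction in the DMSO cultures, where independent lists share 10.1, 16.7, 63.5 and 651.

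Single libraries stood apart from their group for 7 of 281 groups of values, where chance gives about 1 in 20, or 14, and 6 of these are given here. Fgd3 was at 18.6 RPKM in D3 at 2 h (others 22.4 to 22.7, n = 4). Tnf was at 1300 RPKM in D4 at 1 h (others 1920 to 2470, n = 7). Il1a was at 0.463 RPKM in D6 at 0 h (others 0.0669 to 0.17, n = 7). Cd300lb was at 7.67 RPKM in D6 at 1 h (others 12.8 to 16.2, n = 7). Cry2 was at 0.916 RPKM (others 1.52 to 2.07, n = 7) and Cxcl3 at 0.389 RPKM (others 0.0199 to 0.0659, n = 7) in D4 at 0 h.

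The LPS response at 2 h differed by treatment for 11 genes, with values on the log2 scale. It was lower under MPH for Pde4b (-2.64), Sik1 (-2.57), Zfp36 (-2.10), Btg2 (-2.0), Nuak2 (-1.87), Grasp (-1.54), Cdkn1a (-1.51), Zcchc14 (-1.50) and Hs6st1 (-1.02). It was higher for Plet1 (2.56) and Cdyl (0.98). For Btg2, Nuak2 and Zcchc14 the 2 h levels with MPH and DMSO were close, and none of the 11 calls held in every removal of a culture.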

How the results depend on the processing

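Removal of single libraries, removal of the shallowest libraries and sex as a covariate were chosen only after the result was seen, and the other settings before the data were examined. Where a count moved, the cause was not tested.

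MPH against DMSO at 0 h gave 56 genes with no filter on low values, 209 with library weights, 256 and 213 against all 7 DMSO cultures with and without a covariate, and 186 with sex as a covariate. At 1 h it gave 4 and 1 against all 7, and 62 without M4 at 1 h and the 2 shallowest D libraries. At 2 h it gave 266 with weights, 405 and 335 against all 7, 23 with the libraries of that time alone and 241 with sex. D3 with M3 and D4 with M4 share only a number, and with that number as a block the counts were 891, 161 and 803.

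LPS in DMSO gave 1206 genes at 1 h after median-of-ratios scaling, 1371 after quantile normalization, 4346 with weights, 5459 with the culture as a block, 1333 without the covariate, 406 with D3 to D6 alone and 1198 without the 3 libraries below 10 M reads. At 2 h D3 to D6 alone gave 2490. LPS in MPH gave 1236 at 1 h with the culture as a block and, at 2 h, 1412, 1322 and 5577 with median-of-ratios, quantile and block. The difference in LPS response at 1 h gave 2 genes with pseudocount 1, 1 with median-of-ratios, 2 with quantile, 1 with weights, 20 with the block, 5 with sex and 1 without M4 at 1 h and the 2 shallowest D libraries. The culture as a block changed no other call of a gene named here, or of a list by camera, than those given beside the results. It did move counts of list members past the threshold. At 1 h of LPS in DMSO 1 cell cycle gene was then higher and 11 lower, and 1 LXR target higher and 4 lower. In MPH at 1 h 2 cholesterol biosynthesis and 2 cell cycle genes were higher. For the difference in response at 2 h 4 cAMP/CREB targets and 3 NF-kB genes were lower. Counts of other lists moved as well. At 2 h the difference in response gave 17 with weights, 146 with the block and 26 with sex.

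Without any 1 culture or library the counts ran from 31 to 165 at 0 h, 0 to 137 at 1 h and 1 to 215 at 2 h for MPH against DMSO. They ran from 147 to 322 and 819 to 2190 for LPS in MPH, and 0 to 3 and 0 to 15 for the difference in response, at 1 and 2 h each. For LPS in DMSO only whole cultures were left out, and the counts ran from 1237 to 2566 at 1 h and 4625 to 6060 at 2 h. Il1b at 0 h was 1.79 higher against all 7 DMSO cultures (exact permutation p = 0.025), and at 2 h 1.45 to 1.83 without any 1 culture (exact permutation p = 0.1 or 0.0667). Both tests take the cultures as interchangeable, which may not hold.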

Other observations

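Genes called with MPH alone overlapped genes that LPS raises, in a test chosen only after the lists of genes were seen. Of 60 genes higher with MPH at 0 h and tested in both sets of cultures, 30 also rose at 1 h of LPS in UKD, r1 and r2, where independent lists share 2.96 (one-sided Fisher p = 7.43e-24). They include Zfp36, an mRNA decay factor gene (1.95 with MPH, 4.73 with LPS), Pim1 (1.84 and 4.14), Btg2 (2.02 and 3.47), Ier3 (1.92 and 3.57), and the receptor genes Plaur (1.55 and 1.53) and Adora2b (2.56 and 1.58). Trib1 (1.79 and 2.76) and Bcl2l11 (1.27 and 2.63) rose in both as well. Of 20 genes lower with MPH, 10 rose with LPS, where independent lists share 0.985 (one-sided Fisher p = 9.1e-09). Ccl3 (-3.31 and 4.52), Rasgef1b (-2.36 and 4.11), Kcnj2 (-2.07 and 1.87), Ptger4 (-1.69 and 1.72) and Cpeb4 (-1.23 and 1.37) were among these. Genes that fell at 1 h of LPS were not shared beyond chance, with 7 among the higher (6.41 by chance, exact Fisher p = 0.463) and 2 among the lower (2.14 by chance, exact Fisher p = 0.646). The MPH genes and the LPS genes come from separate libraries. The overlap could still reflect that inducible genes vary more than others. Fisher's test also takes genes as independent, which correlated genes from few cultures are not, so its p-values are too small. At 0 h the 200 genes that rose most did not pass in 1 direction (camera adjusted p = 0.388 with an estimated correlation, fry adjusted p = 0.476). They did pass for change in either direction (fry mixed adjusted p = 1.67e-08).

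The gene Xist was above Ddx3y in the cultures D4 and M3 alone, so these 2 cultures carry the mark of female cells and the other 8 that of male cells.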
